A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

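The deposited count table gives raw read counts per gene, made by the authors with featureCounts against genome build R64, per the submitters' processing notes. The deposited TPM table gives values in TPM, which the authors computed from the same libraries, per the submitters' processing notes. Those notes also name DESeq2, and the versions of featureCounts and DESeq2 and the strand setting are not given in the sources used here. The count table held 7126 genes, and 6737 genes had TPM values. The 389 genes missing from the TPM table held 818 of 522650818 counts. RNA was polyA RNA, and mitochondrially encoded genes stayed low (COX1 0.56 to 1.80 CPM, OLI1 0.25 to 1.51 CPM), so they were not interpreted.

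Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the default filter on low counts by group, and a quasi-likelihood fit with robust settings to all 24 libraries with 1 coefficient per group. Each of 15 contrasts was tested by F test, and a joint F test covered the change in strain difference at 12, 48 and 72 h. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, and every adjusted p for a gene is from edgeR unless DESeq2 or limma is named. Fold changes are log2 ratios with standard errors from the F statistic. Gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and beside it an estimated one, adjusted over 33 lists within each contrast. The term adjusted over the list alone means that the correction covered only the members of that list. The contrasts, the gene lists, the thresholds and all alternatives but those named as chosen later were chosen before the data were examined.

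Genes named in the text are the 6 with the largest rise and the 6 with the largest fall among called genes with a standard name, a mean of at least 10 CPM in 1 group and no overlap between the libraries of the groups, for crz1 and crz1 cnb1 at 72 h against 0 h and for the strains at 12, 48 and 72 h. Chance gives no overlap of 3 against 3 libraries for 10% of genes. Up to 4 members with the smallest p per list and contrast were added. HXT9, MRPL11, COX23, COA4, MIA40, SEO1 at 72 h and ARN2 between strains at 0 h fall outside this rule and were chosen after their values were seen. Some genes that the rule names are not reported here.

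The replicate numbers were tested as pairs once, by correlating the deviations of libraries with the same number from their group means. By this check, which set a lower limit for each pair, the numbers paired the libraries for crz1 at 12 h against 0 h (lowest correlation across genes 0.114). They also did for the strains at 0 h (0.56) and 12 h (0.169), and the other comparisons did not pass. For the strains at 48 h only replicate 3 missed the limit (0.0954, against 0.66 and 0.51). The mean there was 0.42, against 0.36 at 12 h, so those libraries cannot be taken as unpaired. Genes are not independent replicates in these correlations.

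The alternatives were RLE size factors, no filter on low counts, the replicate number as a block over all libraries or within strain, a fit of only the libraries compared, DESeq2 1.42.0 (Wald test), limma with a trend on log2(TPM + 1) and log2(TPM + 0.1), an estimated correlation for lists, and each library left out in turn. On the TPM scale fold changes of low genes are understated by the pseudocount. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

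The procedure was tested on simulated data with 200 changed genes. The simulated libraries were independent, without batches shared by number or outlying libraries, and most genes were unchanged. The rates below may therefore not carry over to the real data. For crz1 at 12 h against 0 h it recovered 28.4, 80.6 and 98.5% of genes changed 1.5-, 2- and 4-fold, and 3.29% of calls were false. For crz1 at 72 h against 0 h the shares were 41.8, 88.1 and 98.5%, with 1.23% false. For the strains at 72 h they were 38.8, 85.1 and 92.4%, with 0% false by edgeR. For the change in strain difference at 72 h they were 11.9, 62.7 and 89.4%, with 2.63% false.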

Results

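PolyA RNA of haploid budding yeast of the BY4741 background was sequenced in 24 libraries, 3 for each of 8 groups. One strain, crz1, lacked Crz1, the transcription factor that calcineurin activates. The other, crz1 cnb1, also lacked Cnb1, the regulatory subunit of calcineurin, a phosphatase switched on by calcium. Both were sampled untreated (0 h) and after 12, 48 and 72 h in 200 mM CaCl2, with dilution every 12 h to keep the cultures in logarithmic growth. There was no untreated library at 12, 48 or 72 h. Changes from 0 h within a strain therefore cannot be told apart from effects of time in culture and of repeated dilution. The question stated with the deposited data was which changes in chronic CaCl2 stress depend on calcineurin and not on Crz1. Total counts per library were between 21582317 and 22016465, and 6089 genes had enough counts to be tested. Values after ± are standard errors of log2 changes, with n = 3 libraries per group.

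The deleted genes were checked in each library first. CRZ1 (YNL027W, chromosome XIV, 579580 to 581616, build R64) had 0 to 4 counts in each of the 24 libraries. CNB1 (YKL190W, chromosome XI, 82947 to 83550) had 1581 to 3043 counts in the crz1 libraries and 3 to 22 in the crz1 cnb1 libraries. URA3 and LYS2, both deleted, had 0 counts in each library. HIS3, of which part is deleted, kept 836 to 1895 counts, and LEU2, the marker that replaced CRZ1, had 10068 to 33437. MET17, intact in the stated genotype, had 18406 to 47353 counts in crz1 and 9334 to 24750 in crz1 cnb1. Of the genes specific to the other mating type, alpha, MF(ALPHA)1 stayed at or below 1.34 CPM (counts per 1e6 counts of the library) and MF(ALPHA)2 at or below 0.931, while STE3 reached 12.5 CPM and SAG1 lay between 16.5 and 43.7 CPM. Among the libraries, crz1 48 h replicate 1 stood apart from the others of its group on the first principal component (23.6 against -0.32 and -3.05). Replicate 1 of both untreated groups did so too (-21.1 and -19.5, against -38.0 to -39.8 for the other untreated libraries).

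After 12 h in CaCl2, crz1 cells had raised the iron regulon, the genes that Aft1 turns on when iron is scarce. Of 26 measured members 20 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 change of 1.13. The siderophore transporter genes ARN1 and ARN2 rose by 3.26 ± 0.19 and 3.03 ± 0.25, and FIT2 and FIT3, which encode cell wall mannoproteins that hold siderophores, rose by 4.34 ± 0.37 and 6.63 ± 0.53. In the ergosterol pathway, 20 of 25 genes rose (22 adjusted over the list alone, with 1 lower), among them NCP1 3.99-fold and ERG3 by 1.83 ± 0.21. All 7 a-specific genes, which serve mating of this cell type, fell (7 adjusted over the list alone), such as the agglutinin subunit gene AGA2 (-3.65 ± 0.22) and the pheromone protease gene BAR1 (-2.27 ± 0.20). The 4 alpha-specific genes, markers of the other cell type, had a median of -1.19 and were not called as a list (adjusted p = 0.4). Of these, 1 rose and 2 fell (1 and 2 adjusted over the list alone). The rise was lost without crz1 0 h replicate 1 or 12 h replicate 3, and 1 fell without 0 h replicate 2 or 12 h replicate 2. The camera test gave an adjusted p = 7.59e-16 for the iron regulon, which was 0.152 with an estimated correlation. For ergosterol it was 1.35e-11, with an adjusted p = 0.0911 with an estimated correlation, and for the a-specific genes 5.76e-14, with an adjusted p = 0.0409 with an estimated correlation.

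Sulfur assimilation and methionine genes rose in crz1 at 12 h for 14 of 31 members (14 adjusted over the list alone, with 1 lower), 9 without crz1 0 h replicate 2, and without crz1 0 h replicate 1 there was also 1 lower member. CYS3, which makes cysteine, rose by 2.21 ± 0.25 and the sulfate permease gene SUL2 by 1.69 ± 0.24. Among proteasome genes 18 of 32 fell and 2 rose (22 and 3 adjusted over the list alone), for example RPT3 (-0.63 ± 0.12). Without crz1 12 h replicate 3, 10 proteasome genes fell. The list tests gave an adjusted p = 0.000808 for sulfur, 0.354 as the adjusted p with an estimated correlation, and an adjusted p = 0.00012 for the proteasome, 0.537 as the adjusted p with an estimated correlation. The cell wall protein gene CWP1 fell (-2.48 ± 0.32, adjusted p = 8.25e-06). In all, 1950 genes changed in crz1 at 12 h, 1072 higher and 878 lower, of which 305 and 152 changed at least 2-fold. On the deposited TPM scale, where the median of all genes moved by -0.16, 541 were higher and 1307 lower.

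At 48 h the iron regulon was still up in crz1: 21 of 26 members rose and 1 fell (21 and 1 adjusted over the list alone), with ARN1 up by 3.64 ± 0.20, FIT2 by 4.19 ± 0.37 and FIT3 by 5.78 ± 0.51 (5.05 without crz1 48 h replicate 1). Of 9 osmolyte and Hog1-type genes 6 rose (6 adjusted over the list alone). These included GPD1 (1.15 ± 0.19) and GPP2 (2.18 ± 0.17), whose enzymes make glycerol, and the glycerol importer gene STL1 (2.18 ± 0.40, and 0.70 on log2(TPM + 1)). Of the 7 a-specific genes 6 fell (7 adjusted over the list alone), with AGA2 at -3.02 ± 0.21 and BAR1 at -2.08 ± 0.20. The adjusted p for these lists was 1.69e-18 for iron, 0.000533 for osmolytes and 7.95e-12 for a-specific genes. Each call was lost when the correlation was estimated (adjusted p = 0.145, 0.21 and 0.0799 with an estimated correlation). In all, 2041 genes changed, 1206 higher and 835 lower, and 619 passed when only the 6 libraries compared were fitted. On the TPM scale, with the median of all genes moved by -0.33, 389 were higher and 1810 lower.

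By 72 h the largest rises among called genes in crz1 were again in iron uptake. FIT1 (YDR534C) rose by 7.46 ± 0.79, FIT3 (YOR383C) by 6.20 ± 0.52 and the ferric reductase gene FRE2 (YKL220C) by 5.68 ± 0.50, while LSO1, a gene induced by iron limitation, rose by 5.09 ± 1.29 (5.82 without crz1 0 h replicate 1 and 4.3 without crz1 72 h replicate 2). The phosphate transporter gene PHO84 (YML123C) rose by 4.71 ± 0.82, from a mean of 157 to 4101 CPM, and HBN1, a nitroreductase-like gene, by 4.44 ± 0.34. Among genes that the naming rule covers, the falls included the mating genes FUS1 (-4.35 ± 0.39) and AGA2 (-3.26 ± 0.21), the hypoxic cytochrome c isoform gene CYC7 (-3.05 ± 0.73) and PRM5 (-3.02 ± 0.51). HSP30 (-4.23 ± 1.34, adjusted p = 0.0173) and FMP48 (-3.00 ± 1.05, adjusted p = 0.0294) also fell. The HSP30 call was lost without crz1 72 h replicate 1 (adjusted p = 0.0621) or replicate 2 (0.0506). The FMP48 call was lost without crz1 0 h replicate 2 (0.072) or 3 (0.0844) and without 72 h replicate 1 (0.0838), 2 (0.072) or 3 (0.0671), and with only the libraries compared (0.0517) or on log2(TPM + 1) (0.0531).

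Among the fixed lists, the iron regulon at 72 h in crz1 had 22 of 26 members up and 1 down (22 and 2 adjusted over the list alone; 2 down without crz1 0 h replicate 1 or without crz1 72 h replicate 1). All 7 a-specific genes fell (7 adjusted over the list alone), and 6 of 9 osmolyte genes rose (6 adjusted over the list alone), with GPD1 up by 2.08 ± 0.19 and GPP2 by 2.33 ± 0.17. Part of the G1/S and G2/M lists of cell division genes rose as well, and the other cell cycle lists are not reported here. In the G1/S list 10 of 20 rose (10 adjusted over the list alone), among them the cyclin genes PCL1 (2.46 ± 0.34) and CLN2 (1.19 ± 0.18) and RNR1 (2.57 ± 0.44), a ribonucleotide reductase subunit. Without crz1 0 h replicate 1, PCL1 rose by 3.12 and RNR1 by 3.20. In the G2/M cluster 11 of 15 rose (11 adjusted over the list alone), such as the kinase gene KIN3 (0.92 ± 0.13) and the septum chitin synthase gene CHS2 (0.92 ± 0.15). In the phosphate regulon 8 of 17 rose (8 adjusted over the list alone), including PHO81 (1.89 ± 0.22) and the polyphosphate polymerase gene VTC4 (1.67 ± 0.26). In ergosterol synthesis 15 of 25 rose and 1 fell (15 and 1 adjusted over the list alone; NCP1 1.76 ± 0.21), and of 21 Yap1-type oxidative stress genes 10 rose and 2 fell (10 and 2 adjusted over the list alone), with ZWF1 up by 2.25 ± 0.19 and OYE3 by 2.10 ± 0.25. The list tests gave an adjusted p = 3.54e-16 for iron, 2.09e-08 for a-specific, 5.85e-05 for osmolyte, 0.00181 for G1/S, 0.000381 for G2/M, 0.000767 for phosphate, 0.00184 for ergosterol and 0.0178 for Yap1-type genes. None of these 8 calls held: with an estimated correlation the adjusted p was 0.138 for iron, a-specific and osmolyte genes, 0.534 for G1/S and phosphate, 0.394 for G2/M and Yap1-type and 0.479 for ergosterol genes.

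Of 12 tested Crz1 targets, 4 rose and 3 fell at 72 h in crz1 (4 and 3 adjusted over the list alone), with the glucan synthase gene GSC2 up by 1.03 ± 0.16 and the kinase gene CMK2 at -0.95 ± 0.18. The list was not called (adjusted p = 0.321), and 1 fell without crz1 0 h replicate 2 or 3 or without 72 h replicate 1 or 3. The glutathione list, which the published study focused on and which is therefore not independent evidence, had 9 of 21 members up and 2 down (10 and 3 adjusted over the list alone; 8 up and 1 down without crz1 0 h replicate 2 or without 72 h replicate 2 or 3). ECM4 (1.47 ± 0.25), ECM38 (0.97 ± 0.16) and GTT2 (0.91 ± 0.18) rose and GEX2 fell (-1.43 ± 0.33), and the list was not called (adjusted p = 0.132). In all, 2578 genes changed at 72 h, 1375 higher and 1203 lower, with 405 and 269 at least 2-fold. On the TPM scale the split was 890 higher and 1352 lower.

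Between 12 and 72 h, fewer genes moved in crz1. Of 21 cell wall integrity genes 2 rose (4 adjusted over the list alone): CWP1 by 2.56 ± 0.32 and SED1 by 1.32 ± 0.23, both cell wall mannoproteins. SED1 was not called when only the libraries compared were fitted (adjusted p = 0.0702). The list test gave an adjusted p = 1.49e-05, and an adjusted p = 0.241 with an estimated correlation. The total was 115 genes, 69 higher and 46 lower. It was 32 without crz1 12 h replicate 2, 32 without 12 h replicate 3, 43 without 72 h replicate 1 and 30 without 72 h replicate 3. DESeq2 gave 125 higher and 147 lower, and the TPM scale 52 higher and 21 lower.

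**Figure D1:**
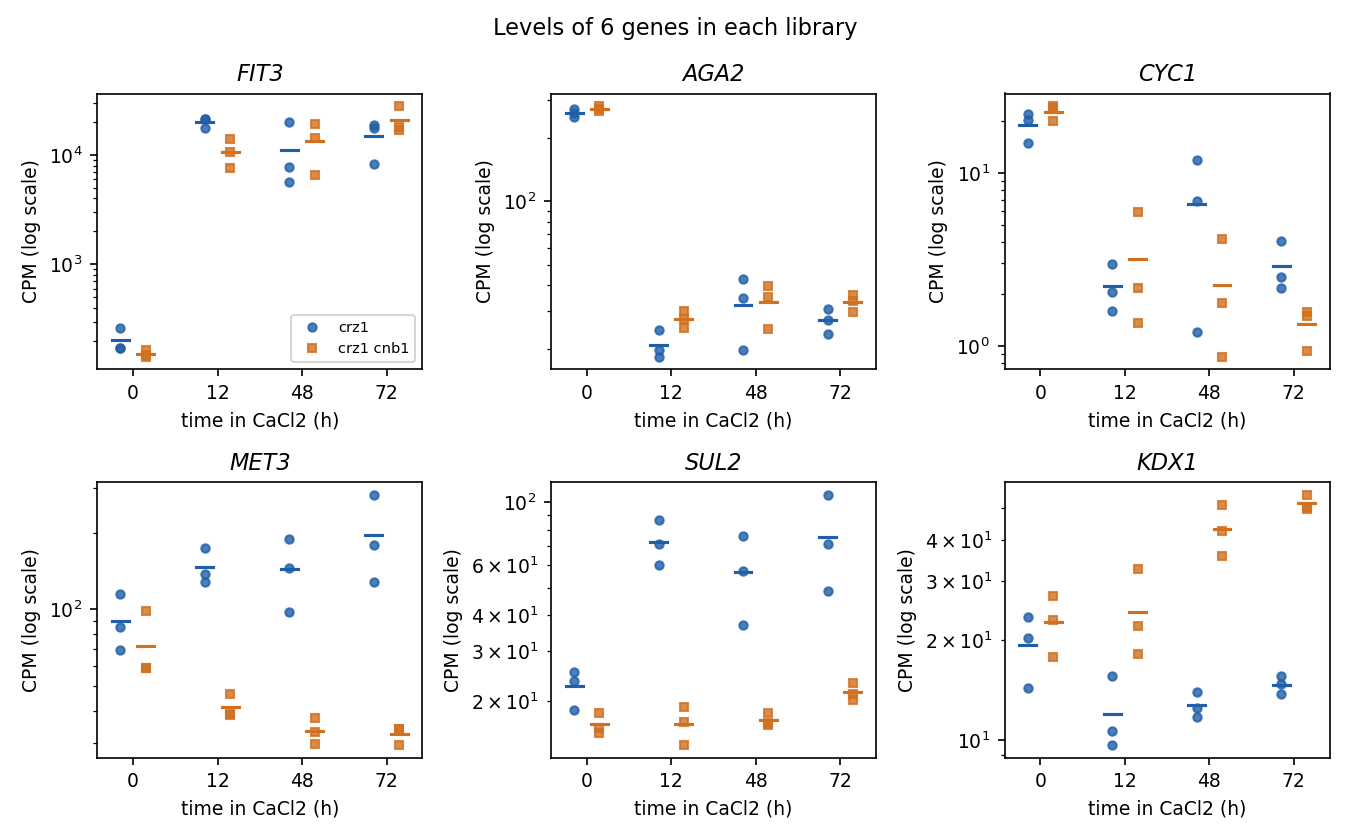
Levels of 6 genes in CPM (log scale) against hours in CaCl2, with 1 point per library and a bar at the mean of 3 libraries, for crz1 (blue circles) and crz1 cnb1 (orange squares). FIT3 was higher and AGA2 lower in every treated library than in the untreated ones, and MET3, SUL2 and KDX1 separated the strains at 72 h.

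In crz1 cnb1 cells the iron regulon also rose at 12 h, for 22 of 26 members with 1 lower (23 and 1 adjusted over the list alone). ARN1 rose by 3.33 ± 0.20 and FIT3 by 6.14 ± 0.52. Of the 7 a-specific genes 6 fell (7 adjusted over the list alone), with AGA2 at -3.31 ± 0.21 and BAR1 at -1.66 ± 0.19. Of the 4 alpha-specific genes of the other cell type, 3 fell too (3 adjusted over the list alone; list adjusted p = 0.0136, and 0.0509 without crz1 cnb1 12 h replicate 3), with adjusted p = 0.0884 with an estimated correlation. Of these genes, MF(ALPHA)1 and MF(ALPHA)2 were near the floor in crz1 cnb1, with means of 0.986 and 0.770 CPM untreated and 0.146 and 0.0655 CPM at 12 h. Nuclear genes of the respiratory chain and ATP synthase fell for 16 of 35 members and 2 rose (20 and 2 adjusted over the list alone). Examples were COR1 and RIP1, subunits of the cytochrome bc1 complex (-0.83 ± 0.13 and -1.51 ± 0.34), and cytochrome c, CYC1 (-2.84 ± 0.61, and -3.69 without crz1 cnb1 12 h replicate 3). The number of respiratory genes that fell was 8 without crz1 cnb1 0 h replicate 2, 7 without 0 h replicate 3, 6 without 12 h replicate 1 and 9 without 12 h replicate 2. Adjusted p values were 7.64e-29 for iron and 3.47e-14 for a-specific genes, both with adjusted p = 0.0347 with an estimated correlation, and 5.44e-07 for respiration, with adjusted p = 0.632 with an estimated correlation. In all, 1251 genes changed, 784 higher and 467 lower. The count was 690 without 0 h replicate 2, 673 without 0 h replicate 3 and 826 without 12 h replicate 1, and on the TPM scale 345 were higher and 574 lower.

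At 48 h in crz1 cnb1, 23 of 26 iron regulon genes had risen and 1 had fallen (23 and 1 adjusted over the list alone), ARN1 by 3.92 ± 0.20 and FIT3 by 6.45 ± 0.53. All 7 a-specific genes fell (7 adjusted over the list alone), such as AGA2 (-3.05 ± 0.21) and the pheromone receptor gene STE2 (-1.62 ± 0.21). Respiratory genes fell for 16 of 35 (20 adjusted over the list alone), with COR1 at -1.30 ± 0.13, QCR2 at -1.25 ± 0.15 and RIP1 at -2.12 ± 0.35. The adjusted p was 6.65e-33 for iron and 9.09e-18 for a-specific genes (adjusted p = 0.0178 and 0.0119 with an estimated correlation) and 3.09e-08 for respiration (adjusted p = 0.922 with an estimated correlation). In all, 1453 genes changed, 872 higher and 581 lower, against 961 without crz1 cnb1 0 h replicate 2 and 907 without 0 h replicate 3.

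At 72 h the 6 largest rises among called genes in crz1 cnb1 were all in iron uptake genes or genes induced with them: FIT1 (7.82 ± 0.80), FIT3 (7.10 ± 0.54), LSO1 (7.02 ± 1.42), FRE2 (5.83 ± 0.50), FIT2 (5.16 ± 0.39) and the reductase gene FRE5 (5.11 ± 0.52). Among genes that the naming rule covers, the falls included CYC1 (-4.07 ± 0.67), FMP48 (-4.01 ± 1.12), HSP30 (-4.54 ± 1.35), ISF1 (-3.98 ± 1.16) and the mating genes AGA1 (-3.22 ± 0.29) and FUS1 (-3.13 ± 0.36). The HSP30 call was lost without crz1 cnb1 72 h replicate 2 (adjusted p = 0.0527) or 3 (0.0532), and the ISF1 call without 72 h replicate 1 (0.0505). By list, 23 of 26 iron genes rose and 2 fell (23 and 2 adjusted over the list alone; ARN1 4.02 ± 0.20), and all 7 a-specific genes fell (7 adjusted over the list alone; AGA2 -3.05 ± 0.21). Respiratory genes fell for 22 of 35 and rose for 2 (26 and 2 adjusted over the list alone), among them RIP1 (-2.48 ± 0.36), COR1 (-0.96 ± 0.13) and QCR2 (-0.89 ± 0.15). Without crz1 cnb1 0 h replicate 2 or without 72 h replicate 3, 1 respiratory gene rose.

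Cytosolic ribosomal protein genes fell at 72 h in crz1 cnb1 for 71 of 137 members and rose for 2 (84 and 3 adjusted over the list alone), for example RPL18B (-0.70 ± 0.13). That number was 42 without crz1 cnb1 0 h replicate 2 (1 higher), 34 without 0 h replicate 3, 38 without 72 h replicate 1 and 39 without 72 h replicate 2. The fall was not confined to this strain. Of 80 genes of the Gene Ontology term cytosolic large ribosomal subunit, 22 fell and 3 rose in crz1 at 72 h, against 39 and 1 in crz1 cnb1. That term was chosen after the results were seen. By camera with an estimated correlation it was not called (adjusted p = 0.986 and 0.987). In the G2/M cluster 8 of 15 rose (9 adjusted over the list alone), with KIN3 up by 1.04 ± 0.13. The adjusted p was 1.51e-23 for iron, 4.49e-10 for a-specific, 6.42e-08 for respiration, 1.46e-11 for ribosomal protein and 0.0113 for G2/M genes. None of these 5 held with an estimated correlation (adjusted p = 0.081 for the first 2 with an estimated correlation, 0.673 for respiration and G2/M and 0.743 for ribosomal protein genes). Of 21 glutathione genes, a list that is not independent evidence here, 6 rose and 2 fell (7 and 3 adjusted over the list alone; 5 and 1 without crz1 cnb1 0 h replicate 2 or without 72 h replicate 3), and the list was not called (adjusted p = 0.624). CYS3 rose by 1.68 ± 0.24 and the glycerol genes GPP2 and GPD1 by 1.54 ± 0.16 and 0.96 ± 0.19, while MET3, which encodes ATP sulfurylase, was at -1.16 ± 0.27. In all, 2175 genes changed, 1222 higher and 953 lower, with 337 and 304 at least 2-fold.

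Between 12 and 72 h in crz1 cnb1, 4 of 21 cell wall integrity genes rose (4 adjusted over the list alone), 2 without crz1 cnb1 12 h replicate 3. RLM1, the transcription factor of the pathway, rose by 1.30 ± 0.18, the kinase-like gene KDX1 by 1.09 ± 0.21 and SED1 by 1.15 ± 0.23 (adjusted p = 0.01, and 0.0692 without 12 h replicate 3). The list had an adjusted p = 0.000672, with adjusted p = 0.512 with an estimated correlation and 0.129 without 12 h replicate 1. In all, 270 genes changed, 128 higher and 142 lower, and on the TPM scale, where the median of all genes moved by 0.13, 161 were higher and 62 lower. The total was 418 without 12 h replicate 1, 126 without 12 h replicate 2, 26 without 12 h replicate 3, and 54, 41 and 91 without 72 h replicates 1, 2 and 3.

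The responses of the strains overlapped. At 72 h, 934 genes were higher and 507 lower against 0 h in both strains, where 276 and 188 would be shared by chance, and 14 genes changed in opposite directions. At 12 h the shared genes were 624 higher and 288 lower (138 and 67.3 by chance), with 2 opposite. At 48 h they were 608 and 331 (173 and 79.7 by chance), with 9 opposite. These chance numbers take the strains as independent, although libraries with the same number and time deviated together.

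**Figure D2:**
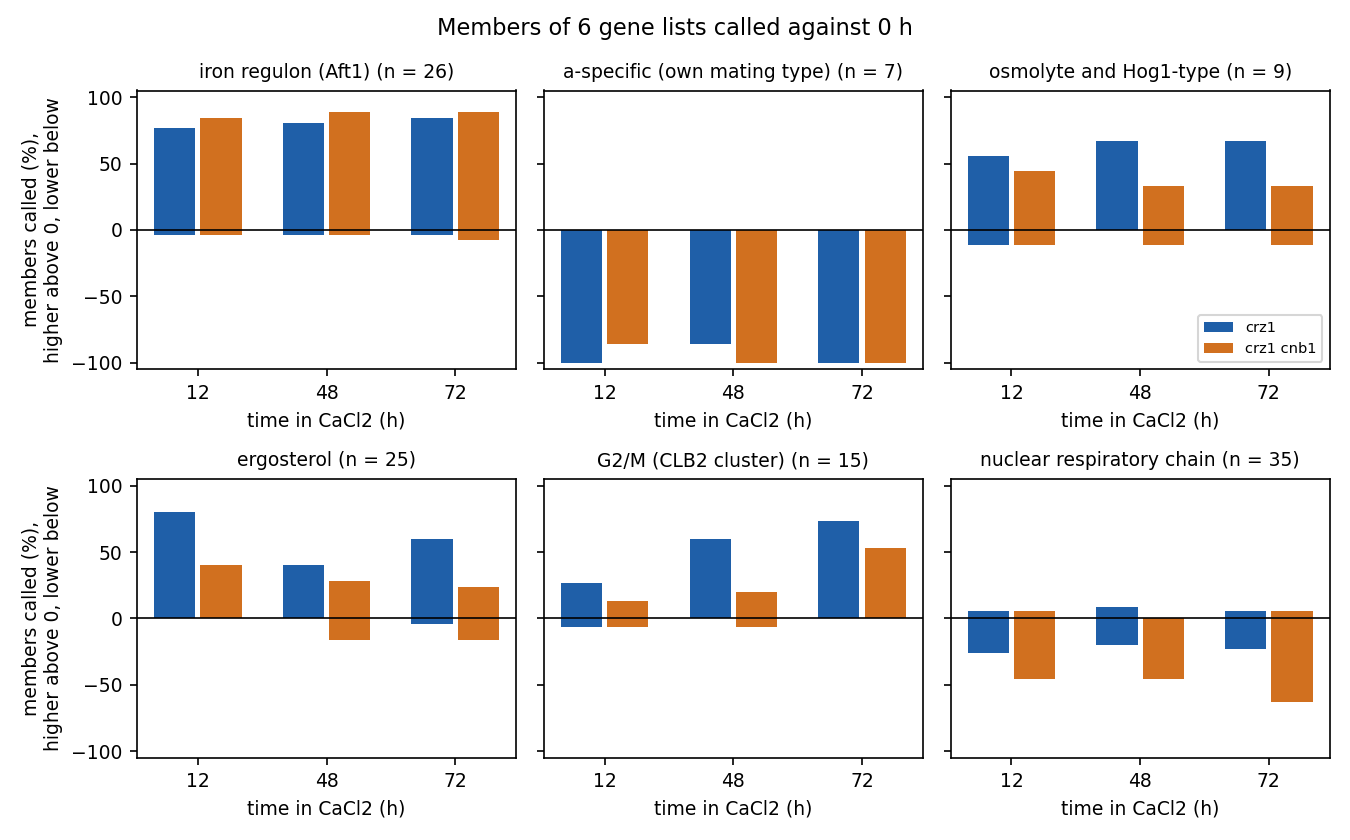
Share of the measured members of 6 gene lists called against 0 h (percent, higher above the axis and lower below), at 12, 48 and 72 h in crz1 (blue) and crz1 cnb1 (orange). The iron regulon rose for 20 to 23 of 26 members in every case, and respiratory genes fell for 22 of 35 members in crz1 cnb1 at 72 h.

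The comparison of the strains at each time addressed calcineurin without Crz1. Untreated, CNB1 itself was called (log2 difference 7.82 ± 0.30, and 8.49 without crz1 cnb1 0 h replicate 2; adjusted p = 6.31e-14). By unadjusted p below 0.05 there were 99 of 6089 genes, a share under the 0.05 that chance alone would give, and DESeq2 called 1. This fit leaves out the pairing by number, although same-number libraries correlated at 0.56 to 0.77 at 0 h. The few calls therefore do not show that the untreated strains match. With the replicate block within time 2 genes passed, the other being the siderophore transporter gene ARN2 (0.99 ± 0.15, adjusted p = 0.0139), named after its value was seen (0.981 without the block). The sulfur assimilation list leaned higher in crz1 by a median of 0.21 (adjusted p = 1.88e-07, and adjusted p = 0.291 with an estimated correlation). No single member passed by edgeR, where 6 had an unadjusted p below 0.05, and 0 passed by DESeq2. The genes beside CNB1 on chromosome XI, PXA2, HYM1, DPH2 and ACP1, did not pass either.

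At 12 h in CaCl2, sulfur assimilation and methionine genes were higher in crz1 than in crz1 cnb1: 15 of 31 members differed (22 adjusted over the list alone), with a median of 1.02. The sulfate permease gene SUL2 (YLR092W) was higher by 2.13 ± 0.24, MET2 by 2.13 ± 0.32, MET3 by 1.83 ± 0.27 and MET17, which incorporates sulfide, by 1.42 ± 0.22. Untreated, MET2 was already higher by 1.05, though not called. The list test gave an adjusted p = 5.95e-26, with adjusted p = 0.00122 with an estimated correlation, and 8 members differed without crz1 cnb1 12 h replicate 3. SEO1, a putative permease gene, was higher by 2.74 ± 0.39 and OPT1, an oligopeptide and glutathione transporter gene, by 0.90 ± 0.15. PUT1, YHK8 and PTR2 were higher by 1.99 ± 0.46, 1.95 ± 0.48 and 1.92 ± 0.43. These 3 calls were each lost without crz1 12 h replicate 2 or 3 or without crz1 cnb1 12 h replicate 1, 2 or 3 (adjusted p between 0.0586 and 0.199), and PTR2 was at 1.32 without crz1 12 h replicate 3.

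Lower in crz1 at 12 h were CWP1 (-2.53 ± 0.32), INO1, which makes inositol phosphate (-1.77 ± 0.34), the chaperone gene HSP82 (-1.41 ± 0.30), IMD2 (-1.34 ± 0.30), CUR1 (-1.19 ± 0.22) and NDJ1 (-1.07 ± 0.27). Of 22 heat shock and folding genes 3 were lower (12 adjusted over the list alone), with adjusted p = 3.61e-08 and adjusted p = 0.227 with an estimated correlation. None of them passed without crz1 12 h replicate 2 or 3 or without crz1 cnb1 12 h replicate 3, when the edgeR count fell to 0 (13 at an unadjusted p below 0.05 and 7 by DESeq2 with all libraries). Without those same libraries the calls of HSP82 (adjusted p = 0.0684, 0.108 and 0.09) and IMD2 (0.0807, 0.114 and 0.0817) were lost. INO1 was lost without crz1 12 h replicate 3 (0.067) or crz1 cnb1 12 h replicate 3 (0.0511). NDJ1 was lost without crz1 12 h replicate 2 (0.132) or 3 (0.11) or crz1 cnb1 12 h replicate 2 (0.0683) or 3 (0.134). In all, 227 genes differed at 12 h, 127 higher and 100 lower in crz1, and 457 with the replicate number as a block. The count was 474 without crz1 12 h replicate 1, 58 without replicate 2, 34 without replicate 3, and 79 and 47 without crz1 cnb1 12 h replicates 2 and 3. Only 12 passed when the 6 libraries were fitted alone, a setting in which MET2 (adjusted p = 0.074), CUR1 (0.074), NDJ1 (0.0769), PUT1 (0.107), YHK8 (0.194) and PTR2 (0.193) did not pass.

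At 48 h the sulfur list remained higher in crz1, for 13 of 31 members with 1 lower (19 and 1 adjusted over the list alone), and a median of 0.56. MET3 was higher by 2.11 ± 0.28, MET17 by 1.79 ± 0.22, SUL2 by 1.73 ± 0.24 and SEO1 by 2.66 ± 0.39. The number higher was 4 without crz1 48 h replicate 3 and 6 without any 1 of the 3 crz1 cnb1 48 h libraries, replicates 1, 2 and 3, and the list's adjusted p = 2.60e-12 became an adjusted p = 0.0615 with an estimated correlation. Of 9 osmolyte genes 2 were higher (4 adjusted over the list alone; 5 without crz1 48 h replicate 1), GPP2 by 1.14 ± 0.16 and GPD1 by 1.02 ± 0.19, with a list adjusted p = 0.000137 and adjusted p = 0.202 with an estimated correlation. RTC3 (1.71 ± 0.30), PRM7 (1.71 ± 0.30) and the aromatic aminotransferase gene ARO9 (1.80 ± 0.45) were also higher. Lower in crz1 were CIS1 (-2.28 ± 0.45), KDX1 (-1.76 ± 0.22), ICY2 (-1.51 ± 0.35), ARO5 (-1.32 ± 0.21) and ARG4, which acts in arginine synthesis (-1.27 ± 0.16). The CIS1 call was lost without crz1 48 h replicate 3 (adjusted p = 0.0504), that of ICY2 without crz1 48 h replicate 2 (0.0796) or crz1 cnb1 48 h replicate 1 (0.0722) or 3 (0.0749). ARO9 was at 1.18 without crz1 48 h replicate 3 (adjusted p = 0.215) and was not called without crz1 cnb1 48 h replicate 1 (0.0797), 2 (0.0927) or 3 (0.0908).

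The total at 48 h was 312 genes, 186 higher and 126 lower in crz1, and 48 higher and 480 lower on the TPM scale, where the median of all genes moved by -0.28. It was 1884 without crz1 48 h replicate 1, 160 and 74 without crz1 48 h replicates 2 and 3, and 116, 129 and 108 without crz1 cnb1 48 h replicates 1, 2 and 3. With the 6 libraries fitted alone 6 genes passed, SEO1, MET3, KDX1 and ARG4 among them.

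At 72 h sulfate assimilation genes were again higher in crz1. MET3 (YJR010W) was higher by 2.60 ± 0.28 (197 against 32.3 CPM), MET5 by 2.06 ± 0.33, MET17 4.01-fold, MET14 by 1.89 ± 0.38, SUL2 by 1.81 ± 0.24 and MET10, a sulfite reductase subunit gene, by 1.79 ± 0.25. SEO1, below the level set by the naming rule at this time and named after its value was seen, was higher by 3.24 ± 0.43 (1.53 on log2(TPM + 1)). Of 31 members 14 were higher and 1 lower (19 and 1 adjusted over the list alone), with adjusted p = 1.42e-20 and adjusted p = 0.00535 with an estimated correlation. The number was 11 higher, and 1 fewer lower, without any 1 of crz1 72 h replicates 1 and 3 and crz1 cnb1 72 h replicates 1 and 2. Of 9 osmolyte genes 3 were higher (4 adjusted over the list alone), with GPD1 at 1.29 ± 0.19 and GPP2 at 0.86 ± 0.16. In ergosterol synthesis 8 of 25 were higher (12 adjusted over the list alone), such as ERG7 (0.58 ± 0.10) and ERG10 (0.60 ± 0.12), and 4 without crz1 72 h replicate 1, 3 without crz1 cnb1 72 h replicate 1 and 4 without crz1 cnb1 72 h replicate 2. Of 21 Yap1-type genes 3 were higher (5 adjusted over the list alone), among them SOD2 (0.72 ± 0.13), the mitochondrial superoxide dismutase, and the peroxiredoxin TSA1 (0.81 ± 0.17). NQM1, a gene of the environmental stress list, was higher by 1.43 ± 0.26. The adjusted p was 4.28e-05 for osmolyte and 3.82e-10 for ergosterol genes (adjusted p = 0.0551 for each with an estimated correlation), and 0.0121 for Yap1-type genes (adjusted p = 0.287 with an estimated correlation).

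In the glutathione list, which is not independent evidence here, 3 of 21 members were higher in crz1 at 72 h (5 adjusted over the list alone): OPT1 by 0.68 ± 0.15, GSH1, the first enzyme of glutathione synthesis, by 0.53 ± 0.12, and DUG2 by 0.41 ± 0.12. The list's adjusted p = 0.014 became an adjusted p = 0.0551 with an estimated correlation. The number was 1 without crz1 72 h replicate 1, 5 without crz1 72 h replicate 2, and 0 by edgeR without crz1 cnb1 72 h replicate 1 or 2 (with all libraries 7 were higher at an unadjusted p below 0.05, and 5 by DESeq2). OPT1 lost its call without crz1 cnb1 72 h replicate 1 (adjusted p = 0.0623) or 2 (0.0609), and GSH1 without those (0.0684 and 0.0602) or crz1 72 h replicate 1 (0.0617). DUG2 lost its call without crz1 72 h replicate 1 (0.231) or 3 (0.118) or crz1 cnb1 72 h replicate 1 (0.116), 2 (0.169) or 3 (0.103). OPT1 and GSH1 did not pass on the TPM scale (adjusted p = 0.0941 and 0.167), nor did DUG2 (0.444).

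Lower in crz1 at 72 h were several genes tied to cell wall signalling. Of 21 cell wall integrity genes 5 were lower and 1 higher (5 and 3 adjusted over the list alone), among them KDX1 (-1.81 ± 0.22), PRM5 (-2.46 ± 0.51) and the MAP kinase gene SLT2 (-0.78 ± 0.15), and the list was not called (adjusted p = 0.0642). It was called without crz1 72 h replicate 1 (adjusted p = 0.0363; 4 lower) or 3 (0.0462) and without crz1 cnb1 72 h replicate 1 (0.0287) or 2 (0.0177), in each case with no member higher by edgeR. CIS1 (-3.41 ± 0.48), SRL3 (-2.44 ± 0.54), the drug transporter gene PDR15 (-1.35 ± 0.27) and INO1 (-1.33 ± 0.34) were also lower, and ARO9 was higher (1.80 ± 0.44). SRL3 lost its call without crz1 72 h replicate 1 (adjusted p = 0.0674) or 3 (0.0599). INO1 and ARO9 lost theirs without crz1 72 h replicate 1 or 3 or crz1 cnb1 72 h replicate 1 or 2 (adjusted p between 0.0623 and 0.124). In all, 375 genes differed at 72 h, 171 higher and 204 lower in crz1, and on the TPM scale, with the median of all genes moved by -0.12, 77 higher and 234 lower. The total was 165 without crz1 72 h replicate 1, 178 without crz1 72 h replicate 3, and 145 and 142 without crz1 cnb1 72 h replicates 1 and 2.

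**Figure D3:**
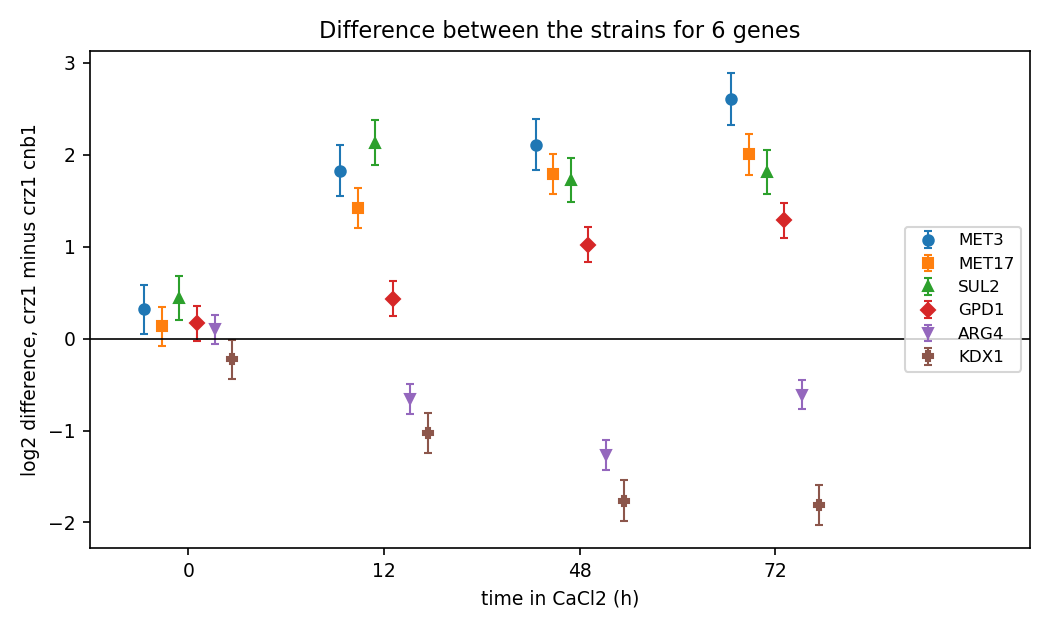
Log2 difference of crz1 minus crz1 cnb1 for 6 genes against hours in CaCl2, where points are fitted values with n = 3 libraries per group and bars are standard errors. MET3 went from 0.32 untreated to 2.60 at 72 h and SUL2 from 0.44 to 1.81, while KDX1 went from -0.22 to -1.81.

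Across the 3 treated times, 26 genes were higher in crz1 each time, where 0.109 would be by chance, and 34 were lower each time, where 0.0693 would be. These chance numbers take the times as independent. A lasting difference between the cultures of the strains would also give more shared genes than that. The deleted gene CNB1 itself is 1 of the 26. SUL2, MET3, MET17, MET2, SEO1 and OPT1 were among the others, and KDX1 and ARG4 among the 34. Untreated, MET2 was already higher in crz1 by 1.05 and SEO1 by 0.87, though neither was called. For MET2 this is close to its 1.09 at 48 h and 1.18 at 72 h. SUL2, MET3, MET17 and OPT1 were higher untreated by 0.44, 0.32, 0.13 and 0.016.

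Whether the strains differed in their response to CaCl2 was tested as the change in the strain difference from 0 h. At 72 h, MET3 (2.29 ± 0.38) and MET17 (1.87 ± 0.30) differed toward crz1 (adjusted p = 0.0082 for both), as did MET10 (1.67 ± 0.35, adjusted p = 0.027), and KDX1 differed the other way (-1.59 ± 0.30, adjusted p = 0.0135). With 1 library left out in turn, the MET10 call was lost for 7 of 12 libraries and the KDX1 call for 4 of 12. MET3 and MET17 rose from 0 h in crz1 and fell in crz1 cnb1, and KDX1 rose in crz1 cnb1 and was not called in crz1. Of 31 sulfur genes 3 differed in response (10 adjusted over the list alone, with 1 the other way; 5 without crz1 72 h replicate 2), and the list's adjusted p = 2.78e-08 became an adjusted p = 0.115 with an estimated correlation. The osmolyte list leaned the same way by a median of 0.57 (adjusted p = 0.000385, and adjusted p = 0.132 with an estimated correlation). No osmolyte member passed by edgeR (4 at an unadjusted p below 0.05 and adjusted over the list alone, and 3 by DESeq2), but 1 did without crz1 0 h replicate 3 and 2 did without crz1 72 h replicate 2. In all, 36 genes differed in response at 72 h, 5 toward crz1 and 31 the other way. The number was 9 without crz1 0 h replicate 2, 87 and 3 without crz1 72 h replicates 2 and 3, 10 without crz1 cnb1 0 h replicate 1, and 11, 13 and 58 without crz1 cnb1 72 h replicates 1, 2 and 3. DESeq2 gave 74 toward crz1 and 99 the other way.

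At 48 h, 26 genes differed in response, 7 toward crz1 and 19 the other way, among them ARG4 (-1.36 ± 0.22), MET17 (1.66 ± 0.30), KDX1 (-1.54 ± 0.30) and MET3 (1.79 ± 0.38). The number was 918 without crz1 48 h replicate 1, 5 without crz1 48 h replicate 2 or 3, 7 without crz1 cnb1 0 h replicate 2 or 3, 3 and 1 without crz1 cnb1 48 h replicates 1 and 2, and 1 without crz1 0 h replicate 2. It was 0 by edgeR without crz1 0 h replicate 3, crz1 cnb1 0 h replicate 1 or crz1 cnb1 48 h replicate 3 (with all libraries, 924 had an unadjusted p below 0.05 and DESeq2 called 97, 50 toward crz1 and 47 the other way). On the TPM scale, where the median of all genes moved by -0.31, 5 and 70 were called.

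At 12 h, 3 genes differed in response, of which HXT9 and MRPL11 are named here after their values were seen: the hexose transporter gene HXT9 (2.66 ± 0.48), CWP1 (-2.38 ± 0.43) and the mitochondrial ribosomal protein gene MRPL11 (-0.72 ± 0.13), each with adjusted p = 0.0408. Leaving out any 1 of the 12 libraries gave 0 by edgeR, except 27 without crz1 12 h replicate 1 (with all libraries, 582 had an unadjusted p below 0.05 and DESeq2 called 34). The sulfur list differed toward crz1 by a median of 0.64 (adjusted p = 2.11e-12, and adjusted p = 0.0489 with an estimated correlation). Of its members 5 passed adjusted over the list alone and 0 by edgeR over all genes (12 at an unadjusted p below 0.05, 3 by DESeq2, and 1 without crz1 12 h replicate 1). The heat shock list differed toward crz1 cnb1, with a median of -0.55 (adjusted p = 4.11e-09, and adjusted p = 0.231 with an estimated correlation). Of these, 2 passed adjusted over the list alone and 0 by edgeR over all genes (11 at an unadjusted p below 0.05 and 1 by DESeq2). Over the 3 times together, 22 genes differed in response by the F test, and 499 did without crz1 48 h replicate 1. The number was 35 and 11 without crz1 12 h replicates 1 and 3, 10 without crz1 cnb1 12 h replicate 2, 14, 14 and 7 without crz1 cnb1 48 h replicates 1, 2 and 3, 11 without crz1 cnb1 72 h replicate 1, and 1 without crz1 0 h replicate 2 or crz1 cnb1 0 h replicate 2. It was 0 by edgeR without crz1 0 h replicate 3, crz1 72 h replicate 3, crz1 cnb1 0 h replicate 1 or 3 or crz1 cnb1 72 h replicate 2 (with all libraries, 686 had an unadjusted p below 0.05 and DESeq2 called 127).

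Of the 176 list calls made over 15 contrasts, 8 held with an estimated correlation: the sulfur list between strains at 12 and 72 h and in the response at 12 h, the a-specific list in crz1 at 12 h and in crz1 cnb1 at 12 and 48 h, and the iron regulon in crz1 cnb1 at 12 and 48 h. The gene p-values rest on the spread between libraries within groups, estimated over all 24 libraries. They take the libraries as independent, although those with the same number and time deviated together. The list p-values ask whether members moved more than other genes, and at the preset correlation they do not measure that spread. Counts of GPP2, HSP82, IMD2, HXT9, TSA1 and RPL18B are uncertain because close paralogs share sequence with them, and counts of overlapping genes are uncertain because the strand setting was not given in the sources used here.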

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

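The gene tests of the change in strain difference were planned, while the tests of shared numbers, depth, matched lists and pairs of libraries were chosen after the results were seen. The values below were singled out, among the tested lists and the genes named in this text, by 1 criterion. The change from 0 h differed between crz1 and crz1 cnb1 in a test of that difference (n = 3 libraries per group). They leave out many of the 3, 26 and 36 genes called at 12, 48 and 72 h. At 72 h, 31 of the 36 went toward crz1 cnb1, and 15 of these were mitochondrial ribosomal protein genes.

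Genes of sulfur assimilation moved higher in crz1 relative to crz1 cnb1: MET3 by 1.79 at 48 h and 2.29 at 72 h, MET17 by 1.66 and 1.87 at those times, and MET10 by 1.67 at 72 h, and the list as a whole by a median of 0.64 at 12 h (adjusted p = 0.0489 with an estimated correlation). At 48 h the glycerol gene GPP2 (1.07) and PRM7 (1.95) also differed toward crz1, as did ERG7 of ergosterol synthesis at 72 h (0.62) and the hexose transporter gene HXT9 at 12 h (2.66). CWP1 at 12 h (-2.38), KDX1 at 48 h (-1.54) and 72 h (-1.59), CIS1 at 72 h (-3.45), and ARO5 (-1.37) and ARG4 (-1.36) at 48 h went the other way. So did 4 genes of mitochondrial biogenesis: MRPL11 at 12, 48 and 72 h (-0.72, -0.74 and -0.74), COX23 at 48 and 72 h (-1.04 and -1.15), COA4 (-1.39 and -1.66) and MIA40 (-1.07 and -1.15). The adjusted p was 0.0408 for the 12 h genes. At 48 h it was 0.0229 for MET17, KDX1, ARG4, MRPL11, COX23, COA4 and MIA40, 0.0371 for MET3, GPP2 and PRM7 and 0.0401 for ARO5. At 72 h it was 0.0082 for MET3, MET17, COX23 and COA4, 0.00904 for MRPL11, 0.0119 for MIA40, 0.0135 for KDX1 and CIS1, 0.027 for MET10 and 0.0459 for ERG7.

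Of these 24 gene values, 3 stayed called without each of the 12 libraries behind them in turn, MET3, MET17 and COX23 at 72 h. These fits had no block for the replicate number, although libraries with the same number and time deviated together. With the replicate block within time, 0 of the named gene values checked lost their call, but not all of the 24 were among those checked. Over all 24 values the adjusted p ran from 0.000663 to 0.196 when 1 library was left out. The 12 h genes were called only without crz1 12 h replicate 1, and MRPL11 and COA4 at 72 h lost their call only without crz1 72 h replicate 3 (adjusted p = 0.0518 for both).

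Sulfur assimilation genes were higher in crz1 than in crz1 cnb1 in CaCl2. Gene length, GC content and expression level are argued against, since the median lay outside the range of matched random lists at 3 of 3 treated times. Such lists lack the correlation between members of the set, so their range is narrow. Untreated, the median lay above it as well (0.21 against an upper end of 0.0898). The median was higher in crz1 in 9 of 9 pairs of libraries with the same number, but it was so in each other pairing of treated libraries as well, so this says nothing about batches shared by libraries with the same number. At 12 and 72 h the lowest median over the 9 pairs of libraries (0.67 and 0.54) lay above the highest over the untreated pairs (0.46). Those pairs reuse 3 libraries per group, so they give no error rate. By camera with an estimated correlation, the list's change in strain difference had adjusted p = 0.0489 at 12 h and 0.115 at 72 h. A difference between the strains already present without CaCl2 is therefore argued against as the whole cause at 12 h, and for the list it is not settled at 72 h. At 48 h such a difference cannot be told apart, since the lowest median there was 0.29. A batch of cultures that differs between the strains also stays open. As a hypothesis, calcineurin may raise sulfate assimilation genes without Crz1, which a calcineurin inhibitor given to crz1 cells would test.

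Taken over the 4 times, libraries of both strains with the same number and time deviated together. Of 1296 ways to match the numbers between strains, 3 gave a mean correlation as large (0.382, highest other 0.396; exact permutation p = 0.00231), the real one included. At 72 h alone the mean was 0.0959 and 2 of 6 ways gave as large a value, so it is not shown for that time. Batches shared by libraries with the same number may explain this, and sequencing depth is argued against because the largest total was 1.02 times the smallest. Which step was shared is not given in the sources used here, and no biological explanation was tested.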

How the results depend on the processing

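The replicate block within time, the fit without both untreated libraries numbered 1 and the DESeq2 likelihood ratio test were tests chosen after the results were seen, and the others were planned. Gene counts not listed moved by at most 1.5 times, no named gene or list value reversed, and the cause of each change was not tested. The balance of higher and lower calls turned in some setting for 12 of 15 counts, for 7 of them on the TPM scale. On log2(TPM + 1) the log2 change shrank by more than 1.5 times for STL1 in crz1 at 48 h (0.70), ISF1 in crz1 cnb1 at 72 h (-2.50), SEO1 between strains at 48 and 72 h (1.48 and 1.53), ARO9 at 48 h (1.06), DUG2 at 72 h (0.27) and HXT9 for the change at 12 h (0.90).

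Fitting only the libraries compared gave 619 genes for crz1 at 48 h against 0 h, 12, 6 and 901 for the strains at 12, 48 and 72 h, and 4 and 215 for the change in strain difference at 48 and 72 h. With the replicate block there were 280 genes for crz1 and 522 for crz1 cnb1 between 12 and 72 h, 457, 714 and 587 for the strains at 12, 48 and 72 h, 9, 65 and 157 for the change in strain difference at those times, and 67 for the joint F test. With the replicate block within strain there were 202 and 429 between 12 and 72 h, 22, 63 and 109 for the change in strain difference, and 48 for the joint test. With the replicate block within time there were 2, 818, 1144 and 919 genes between strains at 0, 12, 48 and 72 h, 90, 415 and 461 for the change in strain difference, and 303 for the joint test.

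The DESeq2 Wald test gave 272 and 532 genes between 12 and 72 h in crz1 and crz1 cnb1, 425 and 589 between strains at 12 and 48 h, and 34, 97 and 173 for the change in strain difference. The likelihood ratio test gave 127 for the joint test. Limma on log2(TPM + 1), with log2(TPM + 0.1) second, gave 73 and 70 genes for crz1 between 12 and 72 h, 136 and 122 between strains at 12 h, 528 and 496 at 48 h, and 1 and 1, 75 and 74, and 67 and 60 for the change in strain difference at 12, 48 and 72 h. Without a filter on low counts 0 genes passed by edgeR for that change at 12 h (3 with it, 582 at an unadjusted p below 0.05). Without both untreated libraries numbered 1 it was 1, 0 and 18 genes by edgeR at 12, 48 and 72 h (924 at an unadjusted p below 0.05 at 48 h), and 0 in the joint test (686). With an estimated correlation 8 of 176 list calls held.

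With 1 library left out in turn, the counts ran from 1487 to 1901, 1417 to 2724 and 2008 to 2537 for crz1 at 12, 48 and 72 h against 0 h and 30 to 152 between 12 and 72 h. For crz1 cnb1 they ran from 673 to 1366, 907 to 1496, 1461 to 2310 and 26 to 418. For the strains they were 1 to 1, 34 to 474, 74 to 1884 and 142 to 489 at 0, 12, 48 and 72 h. For the change in strain difference they were 0 to 27, 0 to 918 and 3 to 87, and 0 to 499 in the joint test.

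Of 165 named gene values, 121 were the same in every setting, 33 lost their call with 1 library left out and 32 in another setting, and ARN2 between strains at 0 h gained one with the replicate block within time (adjusted p = 0.0139). Of 49 list values, 12 were the same in every setting, 2 lost their call with 1 library left out and 36 with an estimated correlation. One of these, alpha-specific genes in crz1 cnb1 at 12 h, also lost it with DESeq2 (adjusted p = 0.0506). The cell wall integrity list between strains at 72 h gained a call without any 1 of 4 libraries, with only the libraries compared (0.0159) and with the replicate block within time (0.0278). No value was given by the DESeq2 Wald test for the joint test, by fitting only the libraries compared for it, which is the same fit, or by the replicate block within strain for the strain comparisons, which could not be fitted.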

Other observations

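The splits of libraries, the mitochondrial ribosomal protein list, the Gene Ontology terms and the tests of matched lists and pairs were tests chosen after the results were seen.

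Mitochondrial ribosomal protein genes were lower in crz1 than in crz1 cnb1 throughout CaCl2. Of 79 tested, 25, 24 and 57 were lower at 12, 48 and 72 h, with medians of -0.42, -0.41 and -0.56 (unadjusted camera p = 0.00572, 0.0095 and 0.00107 with an estimated correlation, for a list made after the pattern was seen). The matching Gene Ontology term, mitochondrial translation, was not called once adjusted with an estimated correlation (adjusted p = 0.493, 0.849 and 0.222 at 12, 48 and 72 h, and 0.395, 0.649 and 0.184 for the change in strain difference). Groups had 3 libraries each. Against 0 h at 72 h, 65 fell and 4 rose in crz1 (median -0.63), while in crz1 cnb1 11 rose (median -0.03). The change in the strain difference had medians of -0.49, -0.46 and -0.65 at 12, 48 and 72 h, with 1, 6 and 15 genes called.

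Genes of actin cortical patches rose in both strains at 72 h, 27 of 46 in crz1 with 5 lower and 30 in crz1 cnb1 with 3 lower (adjusted p = 0.000615 and 1.13e-05). Of 185 genes of the bud neck, 72 rose and 14 fell in crz1 and 73 rose and 7 fell in crz1 cnb1. Of 577 terms, 29 and 35 were called at the preset correlation. By camera with an estimated correlation 0 were called in either strain (adjusted p = 0.986 and 0.987 for actin patches).

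For the lower mitochondrial ribosomal protein genes, 3 technical explanations were tested. Gene length, GC content or expression level is argued against, since the median lay below matched random lists at 3 of 3 treated times. Such lists lack the correlation between members of the set, so their range is narrow. Untreated, the median lay outside it too, on the higher side (0.077 against an upper end of 0.056). A difference between the strains already present without CaCl2 is argued against because the lowest median over the 9 pairs of untreated libraries (-0.0309) lay above the highest over the treated pairs (-0.16). These pairs reuse 3 libraries per group, so they give no error rate. The median was lower in 9 of 9 pairs of libraries with the same number, but also in each other treated pairing, so this says nothing about batches shared by libraries with the same number. A culture batch that differs between strains at each treated time is confounded with the design and stays open. As a hypothesis, calcineurin may lower mitochondrial translation genes without Crz1, which restoring CNB1 in crz1 cnb1 cells would test.

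Other splits of the same libraries were counted for each comparison, and 10 splits cannot give a share under 0.05. For crz1 against 0 h the real split called 1950, 2041 and 2578 genes at 12, 48 and 72 h and the highest other 364, 908 and 0, so that 1 of 10 splits was as large each time. For crz1 cnb1 it was 1251, 1453 and 2175 against 3, 0 and 0, and between 12 and 72 h 115 against 1 in crz1 and 270 against 0 in crz1 cnb1. For the strains it was 1 against 0 at 0 h, 227 against 26 at 12 h and 375 against 1 at 72 h. At 48 h, 312 genes stood against 1690 in another split, so that 2 of 10 were as large. That split put crz1 48 h replicate 1 with crz1 cnb1 48 h replicates 1 and 3, which points to a structure of the samples. The numbers pair the libraries for crz1 at 12 h and for the strains at 12 h, and the other splits that part as many pairs gave 0 genes by edgeR there.

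For the change in strain difference 100 splits were drawn. At 72 h the real split called 36 genes and the highest other 13, with 1 of 100 as large. At 12 h 3 of 100 called as many as the real 3 (highest other 161). The 12 h count is small and did not hold when most libraries were left out in turn. The splits exchange labels at the treated time too, which mixes the treated strains. A low share therefore bears on a strain difference at the treated time, and decides nothing about its change from 0 h. These splits ignore the numbers, which passed the check of pairs for the strains at 0 and 12 h and nearly did at 48 h. Of 32 splits that kept the pairs parted, 5 called as many at 12 h (highest other 26) and 2 at 48 and at 72 h (highest other 34 and 52). Each of these kept the strains apart at the treated time and exchanged untreated labels alone, which leaves the treated difference in place, so they decide nothing about chance. The 24 that exchanged treated labels gave 0 genes by edgeR at each time, but they break up the treated difference, so they cannot decide about its change either. At 48 h 10 of 100 called as many as the real 26 (highest other 1318), and in the joint test 10 of 100 as many as 22 (highest other 1357), so chance is not excluded. With the replicate block within time, 90, 415 and 461 genes were called at 12, 48 and 72 h and 303 in the joint test. Splits with many times the real count point to a structure of the samples.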
